A study of Bos taurus with 4 samples.

How the data were processed

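MicroRNAs (miRNAs) were measured by sequencing in mammary gland tissue of Holstein Friesian cattle, in 1 library labelled control and 3 libraries labelled as infected with Mycoplasma bovis. Per the labels' protocols, total RNA was extracted with Trizol from flash-frozen tissue, ribosomal RNA was removed, and libraries were made with a directional RNA kit. The protocols name no small RNA kit and no size selection, so how the short RNAs were captured is not given in the sources used here. Capture, ligation and PCR favour some short sequences over others, so shares of reads compare libraries with each other and are not molar amounts.

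Per the submitters' processing notes, reads were aligned with Bowtie and the cattle genome build was UMD 3.1. The Bowtie version, the read counter, the miRNA catalogue release and the program that predicted miRNAs without a catalogue name are not given in the sources used here. The authors deposited 1 table of mature miRNAs with a read count and a TPM for each library. Its 615 entries comprise 525 with a catalogue name (prefix bta, for Bos taurus) and 90 predicted ones. The read count columns deposited by the authors hold whole numbers whose totals differ between libraries, and are raw counts. The TPM columns, named so per the file headers, are each count divided by its column total and scaled to the same sum in each library, with no length term. They therefore carry no correction for libraries in which a few miRNAs take most of the reads. The table's column for the control is spelled differently from the sample title, and was matched because no other title resembles it.

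Some mature miRNAs have identical or nearly identical sequences, and a read from one can then be counted under several names. Whether this happened was inferred from the counts alone, since no sequences were compared. Entries with at least 40 reads in total whose counts agreed within 1% in all 4 libraries were taken as such: 11 sets of 2 entries. They include miR-26a with miR-26c, let-7b with miR-3596, miR-199a-3p with miR-3604, and miR-2284j with miR-2312. The second entries of these sets hold 19.5% of the control's counts and 5.63%, 17.0% and 9.36% of those of infected 1, 2 and 3. Such reads therefore appear to enter the library totals more than once. Values of these entries are uncertain as to which miRNA was present.

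The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the deposited counts, with TMM factors and the default filter of filterByExpr (a minimum count of 10 and a minimum total of 15). It kept 407 entries, 386 named and 21 predicted, which hold 99.996 to 99.997% of the reads of each library. TMM factors were 1.17 for the control and 0.787, 1.07 and 1.01 for infected 1, 2 and 3. With 1 control library the spread comes from the infected libraries alone (2 residual degrees of freedom), and the control is assumed to vary like them. The common biological coefficient of variation was 0.526. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. A permutation of 1 library against 3 cannot give a p below 0.25, so no permutation test of a single value is reported.

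Before the data were examined, the grouping, the tests, the alternatives, 11 miRNA lists and the rule for naming miRNAs were fixed. The lists are markers or families: leukocyte, inflammation-responsive, epithelial, lactating mammary gland and milk, stromal and muscle, endothelial, erythroid, let-7, miR-17-92 and paralogues, the imprinted cluster homologous to human 14q32, and the ruminant miR-2284 and miR-2285 families. Lists share members; the inflammation-responsive and leukocyte lists share 4. Each list was tested with camera (limma 3.58.1), which compares its members with all other miRNAs, at a preset correlation between members of 0.01, and again with an estimated correlation. Fry tested whether a list's members moved one way on balance. The percentile of a list's median was taken among 10000 random lists of the same size, matched on mean expression. The naming rule took, in each direction, up to 12 miRNAs past the threshold with a mean of at least 10 CPM (counts scaled to library size) and a control value outside the infected range. Where fewer than 6 qualified, those with the lowest unadjusted p filled up to 6, given as values only. It also took the 10 most abundant miRNAs and, of each list, the 2 to 4 tested members with the highest mean. Levels are TMM-normalised CPM, with the mean and standard deviation (SD) of the infected libraries. Ratios of single libraries to the control add a prior count of 2, which draws low counts towards 0 on the log2 scale. Where a miRNA had few reads, the ratio of pooled infected to control reads is given with its exact 95% interval. Such intervals cover counting error only, since reads without molecular identifiers are not independent molecules. For a miRNA at 0, the floor is 3 counts, or 0.304 CPM in the control and 0.201, 0.272 and 0.342 CPM in infected 1, 2 and 3.

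The alternatives were relative log expression factors, upper quartile factors, library totals alone, scaling without the 5 most abundant miRNAs, no filter, at least 10 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, limma on log2 of the deposited TPM plus 1 or 0.1, and leaving out each infected library. Keeping 1 entry of each near-identical set was added after seeing the data. Names were matched to the RefSeq annotation of the ARS-UCD2.0 assembly (520 of 525 named entries), which served only to find which hairpins neighbour each other. That assembly is not the build of the files, so no coordinates are given.

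The tests were checked on simulated counts for the 407 miRNAs of the infected against control comparison, drawn with the real means, totals and dispersions in 10 draws, with 200 miRNAs changed. Benjamini-Hochberg adjustment is stricter where fewer miRNAs change, so the shares called would then be smaller. edgeR called 9.20% of the miRNAs changed 2-fold, 29.6% of those changed 4-fold, 65.8% at 8-fold and 85.6% at 16-fold, and 1.93% of unchanged ones. In 20 draws of 11 lists over the same miRNAs, camera with the preset correlation called 18 of 20 lists moved 2-fold and 0.909% of unchanged lists with independent members. It called 41.8% of unchanged lists whose members shared a deviation in each library. The estimated correlation called 0 of 20 moved lists and fry 3 of 20, so neither has much power in this design.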

Results

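miRNAs, short RNAs that repress target messenger RNAs, were counted in mammary gland tissue of Holstein Friesian cattle. Mycoplasma bovis is a bacterium without a cell wall that causes contagious mastitis. Infected tissue gave 3 libraries (infected 1, 2 and 3) and tissue labelled control gave 1. The labels do not say whether the libraries came from separate animals, so p-values compare this 1 control library with the infected ones and measure only the spread between these libraries, which may be technical. Counted reads came to 9856002 in the control and to 14949529, 11032507 and 8767110 in infected 1, 2 and 3. At least 1 read was counted for 528 entries in the control and for 500.7 ± 2.89 (SD, n = 3) in the infected libraries. At a minimum of 10 reads the numbers were 369 and 366.3 ± 2.89.

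The first question was which miRNAs made up most of the reads. miR-148a, a miRNA abundant in lactating mammary gland and milk, took 10.97% of the control's summed counts (exact 95% interval 10.95 to 10.99%, for counting error only). In the infected libraries it took 28.4% ± 17.2 (SD, n = 3), with 45.5% in infected 1, 11.1% in infected 2 and 28.6% in infected 3. These sums include the second entries of near-identical sets, 19.5% of the counts in the control and 5.63% in infected 1. Without them the shares of miR-148a would be larger, by the largest factor in the control. miR-30a-5p took 3.97% in the control and 9.31% ± 3.76 in the infected libraries, and miR-143, a miRNA of smooth muscle and fibroblasts, 3.01% and 5.79% ± 2.91. miR-26a, whose reads appear to be counted also as miR-26c, took 17.7% in the control and 9.15% ± 5.07 in the infected libraries. miR-21-5p, which is induced in inflammation and wound repair, took 9.12% and 5.85% ± 2.13. miR-99a-5p took 4.93% and 2.79% ± 2.67, miR-26b 2.35% and 1.55% ± 0.895, let-7i 1.89% and 1.76% ± 1.81, and miR-10b 1.17% and 2.00% ± 0.774. The 10 most abundant entries together held 72.8% of the control's counts and 75.7% ± 5.84 of the infected libraries' counts. With 1 entry kept per near-identical set, the 10 most abundant held 71.0% in the control and 76.0% on average in the infected libraries. For miR-148a, miR-26a, miR-30a-5p, miR-21-5p and miR-10b the normalised control level lay outside the infected range, where chance gives 50% of miRNAs. The margin to infected 2 was narrow for miR-21-5p (77752 CPM in the control against 76428) and miR-10b (9939 against 10353). None of these 10 passed edgeR's quasi-likelihood test. For miR-148a the fitted log2 fold change, infected over control, was 1.78 ± 1.23 (SE), and for miR-30a-5p it was 1.57 ± 0.97.

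**Figure D1:**
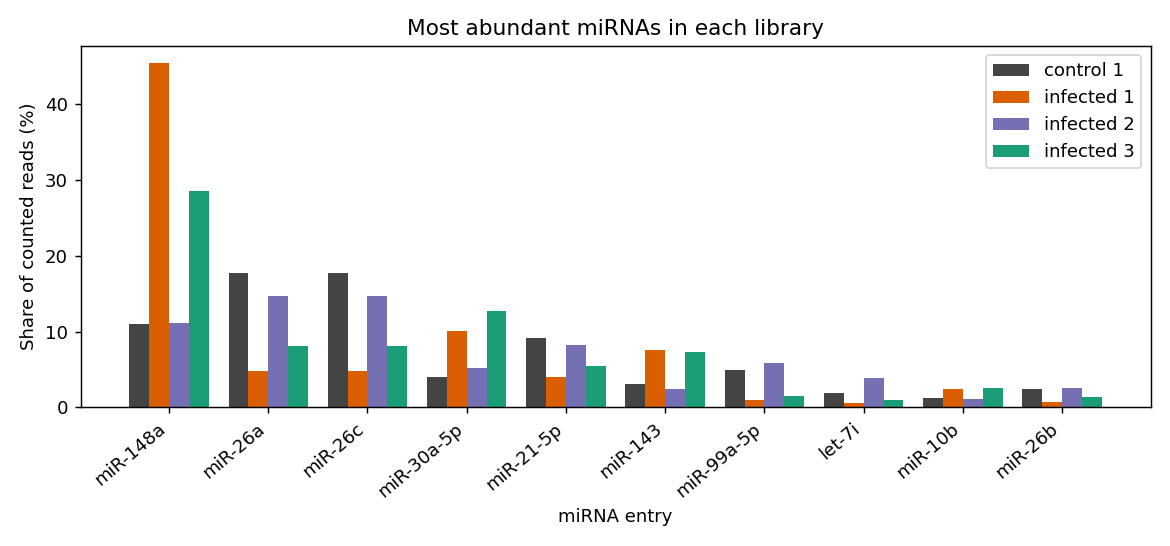
Share of counted reads (%, vertical axis) of the 10 most abundant miRNA entries in each of the 4 libraries, 1 bar per library. miR-148a reaches 45.5% in infected 1 and 11.1% in infected 2, against 10.97% in the control, and the miR-26a and miR-26c bars appear to count the same reads.

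The main comparison asked which miRNAs differed between infected and control tissue. By edgeR's quasi-likelihood test 0 of 407 miRNAs passed, and the smallest adjusted p was 0.9995. At an unadjusted p under 0.05 there were 8 miRNAs, 5 higher and 3 lower in infected tissue, where 20.35 would be expected by chance. limma-voom called 0 (6 at an unadjusted p under 0.05). DESeq2 called 2 (16 at an unadjusted p under 0.05), miR-2284j and miR-2312, both higher, with a log2 fold change of 5.12 and an adjusted p of 0.0466. These entries have the same counts in each library and so were taken as 1 set of reads. DESeq2 adjusted over both, and counting the same reads under 2 names lowers the adjusted p of each. DESeq2 was not run with 1 entry of the set, so no conclusion is drawn from its call. The control had 3 of these reads and infected 1, 2 and 3 had 179, 18 and 90, a pooled ratio of 34.1 (exact 95% interval 11.6 to 166). Infected 2 was also below infected 1 and 3, with a fitted log2 difference of 3.07 between that pair and infected 2.

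The miRNAs with the lowest unadjusted p are given as values, none having passed edgeR's test. Among those higher in infected tissue, miR-27a-5p stood at 30.6 CPM in the control and 95.4 ± 32.9 CPM (SD, n = 3) in the infected libraries. miR-6522 stood at 6.05 and 34.8 ± 21.5 CPM and miR-138, a brain-enriched miRNA, at 5.88 and 16.5 ± 2.97 CPM. miR-6516 had 1 control read, with a pooled ratio of 24.2 (exact 95% interval 4.21 to 971). Among those lower, miR-223, a miRNA of neutrophils and other myeloid cells, stood at 22.4 CPM in the control and 6.18 ± 0.642 CPM in the infected libraries, a log2 fold change of -1.86 ± 0.56 (SE). miR-132, which is induced through CREB signalling, stood at 15.6 and 6.02 ± 0.990 CPM. The control exceeded the infected libraries also for miR-504 (69.3 against 24.1 ± 13.1 CPM), miR-744 (22.8 against 8.31 ± 3.81 CPM) and miR-370 of the imprinted cluster (12.7 against 2.92 ± 1.36 CPM). miR-6530 had 34 control reads and 6 pooled infected reads, a ratio of 0.0629 (exact 95% interval 0.0216 to 0.152). Over the 254 miRNAs with a mean of at least 10 CPM the control lay outside the infected range for 103, where chance gives 50%.

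**Figure D2:**
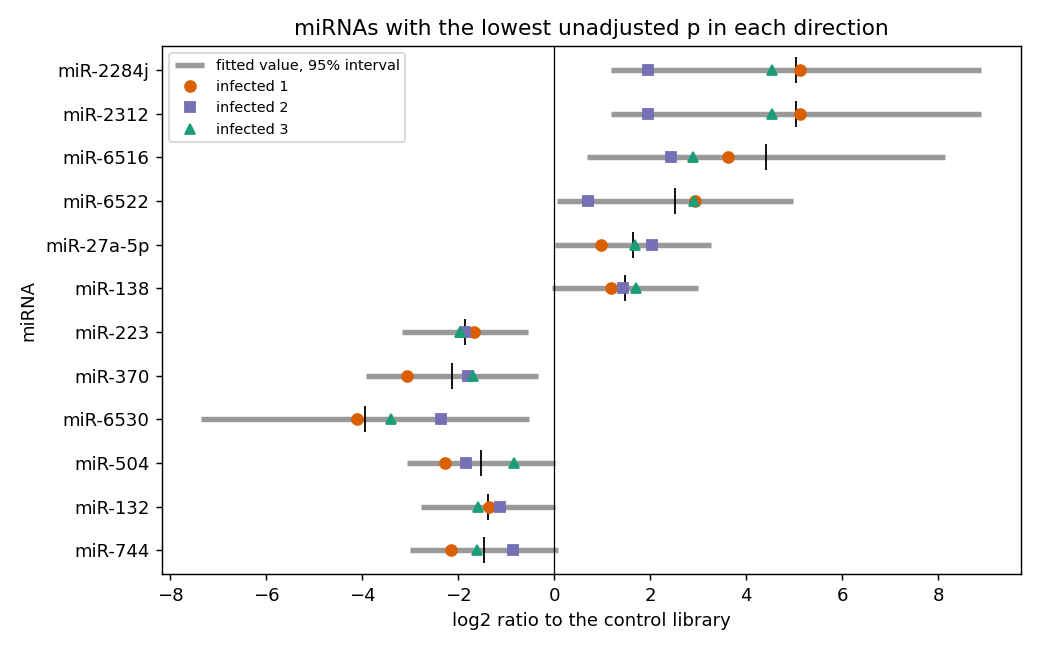
Log2 ratio to the control library (horizontal axis) of the 6 miRNAs with the lowest unadjusted p in each direction. Vertical ticks are fitted values, grey bars their 95% intervals, and symbols the infected libraries, calculated with a prior count of 2; for miR-223 the libraries lie at -1.68, -1.86 and -1.96.

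The count of 0 rested on infected 2. Without it, edgeR called 63 of 394 miRNAs, 33 higher and 30 lower in infected 1 and 3, whereas leaving out infected 1 or infected 3 left 0 calls. Infected 1 and infected 3 resembled each other most, with 16 of the 254 miRNAs differing by more than 2-fold. Infected 2 differed by more than 2-fold from infected 1 in 115 and from infected 3 in 100, but from the control in 39. The control differed from infected 1 in 86 and from infected 3 in 61. Among the calls without infected 2, miR-148a had a log2 fold change of 2.23 and miR-30a-5p of 1.92. miR-143 and miR-145 both stood at 1.75 there, miR-223 at -1.81 and miR-146b at -1.33. Infected 2 set against the same pair in place of the control gave 109 calls by edgeR. They included miR-148a (log2 difference 2.08), miR-143 (1.92), miR-30a-5p (1.38) and miR-146b (-1.09), but not miR-145 (0.89) or miR-223 (0.08).

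**Figure D3:**
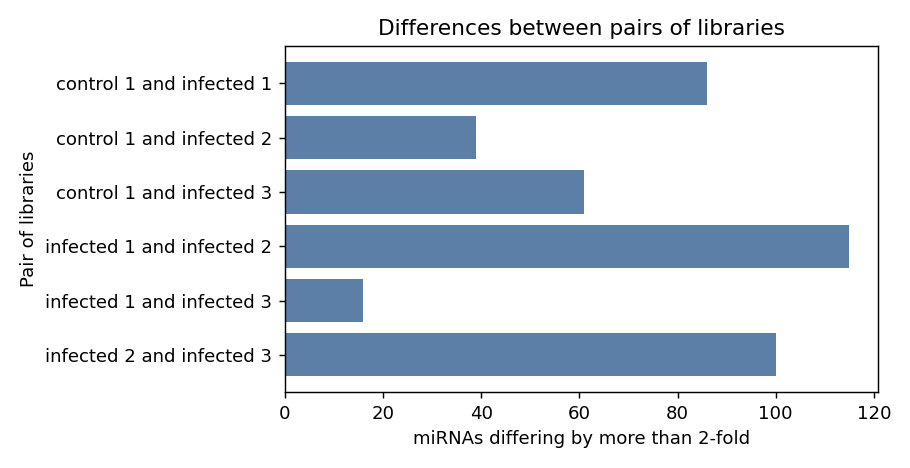
Number of miRNAs, of the 254 with a mean of at least 10 CPM, that differ by more than 2-fold between each pair of libraries (horizontal axis, count). The fewest, 16, separate infected 1 from infected 3, and the most, 115, separate infected 1 from infected 2.

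Lists of miRNAs were compared to ask whether families or markers of cell types moved as groups. Camera with its preset correlation called 5 of 11 lists, 3 higher and 2 lower in infected tissue. With an estimated correlation it called 0, and fry called 0. The medians of the 5 called lists kept their sign with each other scaling. In each of the 11 lists 0 members passed edgeR's test over all 407 miRNAs, and 0 adjusted over the list alone.

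Among the higher lists were the miR-2284 and miR-2285 families, which are specific to ruminants. Of 33 tested members 30 had a fitted value above 0 and 3 below, with a median log2 fold change of 1.18. Camera's adjusted p was 4.93e-05, and the adjusted p was 0.639 with an estimated correlation. The control lay below all 3 infected libraries for 14 of the 33, where chance gives 25%. All members share the 1 control library, so the 14 do not count as separate trials. The list's medians were 0.56, 0.30 and 0.91 in infected 1, 2 and 3. miR-2285t stood at 1001 CPM in the control and 3907 ± 3337 CPM (SD, n = 3) in the infected libraries, miR-2284x at 1233 and 1487 ± 134 CPM, and miR-2285f at 69.1 and 112 ± 16.1 CPM. In infected 2 alone miR-2285t stood at 553 CPM, below the control. The fitted value of miR-2284x fell below 0 with library totals alone and on both TPM scales. The median was carried in part by scarce members. 18 of the 33 had a mean under 10 CPM, and over the other 15 it was 0.37. The list's median was 0.78 without infected 1 and 0.74 without infected 3. Some members are entries of the same near-identical set, such as miR-2285q with miR-2285z, so the 33 are not all separate. With 1 entry kept per set, 29 members were tested and the median was 0.75.

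Stromal and muscle miRNAs had fitted values above 0 for 9 of 14 members and below for 5, with a median of 0.77. The adjusted p was 0.0431 by camera and 0.639 with an estimated correlation. miR-145, a smooth muscle miRNA made from the same transcript as miR-143, stood at 1989 CPM in the control and 5579 ± 1829 CPM (SD, n = 3) in the infected libraries. miR-143 itself stood at 25667 and 63926 ± 37723 CPM, and miR-199b, a fibroblast miRNA, at 3584 and 5520 ± 2193 CPM. The 9 members above 0 also include miR-1 (fitted log2 fold change 0.96), miR-133a (0.92), miR-133b (1.07) and miR-206 (1.62). miR-133b had 6 control reads and miR-206 had 9. The 5 below 0 were miR-199a-3p (-0.64), miR-29a (-0.38), miR-214 (-0.24), miR-499 (-0.11) and miR-29b (-0.05). All 6 erythroid members had fitted values above 0, with a median of 0.74, an adjusted p of 0.0431 by camera and of 0.639 with an estimated correlation. The red cell miRNA miR-451 stood at 148 CPM in the control and 257 ± 73.2 CPM in the infected libraries, and miR-363, which the miR-17-92 list also holds, at 56.9 and 121 ± 52.9 CPM. miR-16a stood at 981 and 1270 ± 258 CPM. The erythroid member miR-144 was scarce, with 3 control reads and 15, 2 and 7 in infected 1, 2 and 3. It lay below the control in infected 2. Without infected 2 the stromal list's camera adjusted p was 0.543 and its median 0.59. Without infected 1, 2 or 3 in turn the erythroid list's adjusted p lay between 0.0987 and 0.148 and its median between 0.54 and 0.89. Neither list passed camera with library totals as the only scaling (adjusted p 0.0729 for both, medians 0.50 for stromal and 0.42 for erythroid miRNAs). The same held with 10 CPM required in 2 libraries (camera adjusted p 0.193 with a median of 0.42 for stromal, and 0.115 with a median of 0.62 for erythroid miRNAs).

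Among the lower lists were the inflammation-responsive miRNAs, which are induced by or feed back on NF-kB and Toll-like receptor signalling. Of 15 tested members 14 had a fitted value below 0 and 1 above, with a median of -0.49. Camera's adjusted p was 2.75e-04, and the adjusted p was 0.639 with an estimated correlation. For 9 of the 15 the control lay above all 3 infected libraries, where chance gives 25%. The members share 1 control library and are correlated (estimated at 0.44), so the 9 do not count as separate trials. The margin to infected 2 was narrow for miR-21-5p (77752 CPM in the control against 76428) and miR-147 (51.4 against 47.8). The medians were -0.93, -0.11 and -1.09 in infected 1, 2 and 3, and the fitted median was -0.32 without infected 1 and -0.83 without infected 2. With library totals alone it was -0.77, and with upper quartile factors -0.32. miR-146b stood at 2267 CPM in the control and 1226 ± 605 CPM (SD, n = 3) in the infected libraries, miR-146a at 2506 and 1781 ± 575 CPM, miR-125b at 2051 and 1651 ± 537 CPM, and miR-223 and miR-132 as given among the lowest p-values.

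miRNAs of the imprinted cluster, homologous to human 14q32, had fitted values below 0 for 34 of 50 members and above for 16, with a median of -0.24. The adjusted p was 0.0431 by camera and 0.759 with an estimated correlation. This list rested on infected 2, whose median was -0.98 against -0.16 in infected 1 and 0.00 in infected 3. Without infected 2 the camera direction reversed, with an adjusted p of 0.935 and a median of -0.03; the median was -0.41 without infected 3, -0.55 with library totals alone and -0.09 with upper quartile factors. The list was not called with no filter (camera adjusted p 0.0538) or with 10 CPM required in 2 libraries (camera adjusted p 0.193). miR-127 stood at 2257 CPM in the control and 2173 ± 1220 CPM (SD, n = 3) in the infected libraries, miR-379 at 2008 and 2373 ± 1322 CPM, and miR-411a at 622 and 453 ± 103 CPM.

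**Figure D4:**
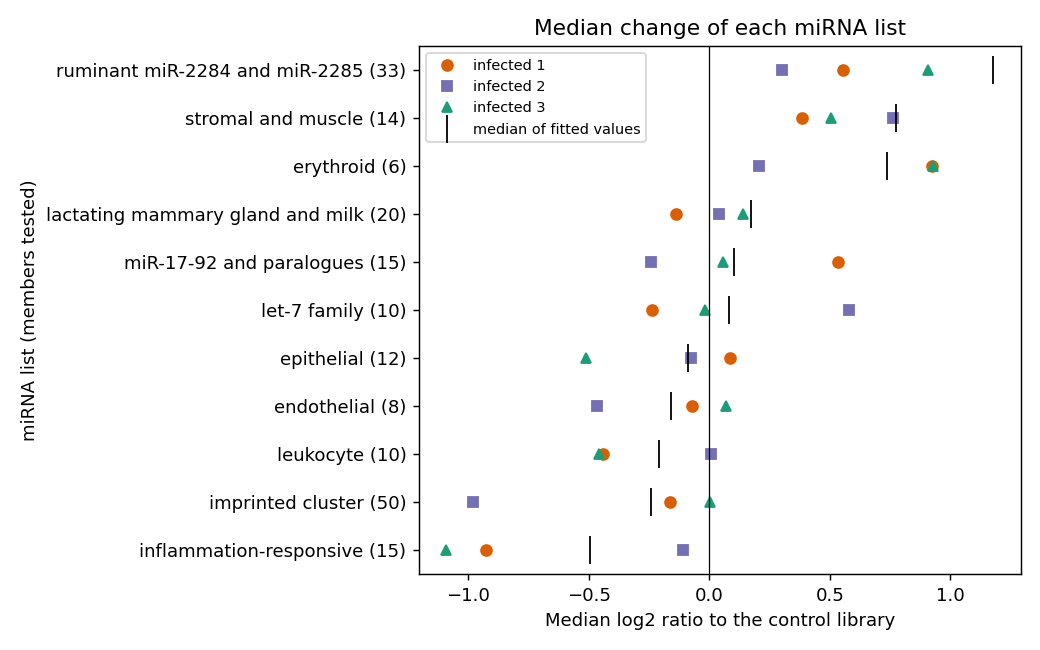
Median log2 ratio to the control library (horizontal axis) over the tested members of each of the 11 miRNA lists, whose numbers stand in brackets. Black ticks are medians of fitted values and symbols those of each infected library, calculated with a prior count of 2; the fitted medians run from -0.49 for the inflammation-responsive list to 1.18 for the ruminant list.

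The other 6 lists were not called by camera. Leukocyte miRNAs had 4 of 10 fitted values above 0 and 6 below, with a median of -0.21 and a camera adjusted p of 0.105. The lymphocyte-rich miR-342 stood at 2243 CPM in the control and 2309 ± 285 CPM (SD, n = 3) in the infected libraries, and miR-142-5p, made in all blood cell lineages, at 1007 and 777 ± 184 CPM. Epithelial miRNAs were split 5 above and 7 below 0. Their median was -0.09, their mean 0.06 and the camera adjusted p 0.877. miR-200c, which maintains epithelial identity, stood at 5525 and 10583 ± 6237 CPM, miR-200a at 4133 and 5168 ± 908 CPM, and miR-182 at 3693 and 3502 ± 1388 CPM. Endothelial miRNAs had 2 of 8 above 0, a median of -0.16 and a camera adjusted p of 0.363; miR-126-3p, the main endothelial miRNA, stood at 17711 and 16609 ± 3199 CPM, and miR-218 at 1625 and 824 ± 358 CPM. Without infected 2 the leukocyte median was -0.54 and the endothelial median 0.08, and without infected 3 the epithelial median was 0.13 and the endothelial -0.26. With library totals alone the 3 medians were -0.49, -0.44 and -0.39 for leukocyte, endothelial and epithelial miRNAs, and the latter 2 turned positive with upper quartile factors.

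The list of lactating mammary gland and milk had 11 of 20 members above 0, a median of 0.17 and a camera adjusted p of 0.554. It holds miR-148a and miR-30a-5p, with higher infected means, and miR-26a and miR-21-5p, with lower ones. The let-7 family had 7 of 10 above 0, a median of 0.08 and a camera adjusted p of 0.766. let-7f stood at 16942 CPM in the control and 14816 ± 2232 CPM (SD, n = 3) in the infected libraries, and let-7a-5p at 7532 and 10002 ± 2124 CPM. miR-17-92 and its paralogues, which promote proliferation, had 9 of 15 above 0, a median of 0.10 and a camera adjusted p of 0.784. miR-25 stood at 2235 and 1703 ± 1253 CPM, miR-106b at 931 and 898 ± 88.7 CPM, miR-20a at 815 and 731 ± 59.7 CPM, and miR-92a at 744 and 830 ± 319 CPM. Without infected 2 the medians were 0.022 for the lactating gland, -0.15 for let-7 and 0.45 for miR-17-92, without infected 1 the last was -0.07 and let-7 0.43, and without infected 3 let-7 was 0.36. With library totals alone the medians of these 3 lists were below 0, as that scaling moved the median of all tested miRNAs by -0.31 and left 39.1% rather than 53.3% with a fitted value above 0. Upper quartile factors moved it by 0.15 and left 64.1% above 0.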

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

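Keeping 1 entry of each near-identical set was chosen only after the data were seen. It was run with edgeR and camera but not with DESeq2, whose calls were the entries of 1 such set. The number of miRNAs called by edgeR's quasi-likelihood test was 0 under each alternative scaling, filter and test except DESeq2, which called 2. Leaving out 1 infected library gave 0 to 63 calls, the 63 without infected 2. No paired analysis was possible because the control has 1 library and the groups share only 1 replicate number. The number of entries detected moved with the minimum and with depth: 528 in the control and 500.7 on average in infected libraries had at least 1 read, 369 and 366.3 at least 10 reads, and 523 and 494.3 at least 1 read after thinning to the smallest total. The control had more at 1 read before and after thinning. Depth limits single scarce miRNAs, such as miR-6516, whose 1 control read leaves a ratio anywhere from 4.21 to 971. In the simulated comparison 29.6% of 4-fold changes were called, so most changes of that size would be missed.

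Of the 5 lists that camera called with its preset correlation, 2 remained called under each other scaling and filter, limma-voom, the collapsed entries and each left-out library: the ruminant and the inflammation-responsive lists. With an estimated correlation 0 lists were called, with adjusted p of 0.639 for the inflammation-responsive, stromal, erythroid and ruminant lists and 0.759 for the imprinted cluster. With fry 0 were called, with 0.510 for the same 4 lists and 0.864 for the imprinted cluster. Library totals alone left 3 lists (camera adjusted p 0.0729 for stromal and 0.0729 for erythroid). A minimum of 10 CPM in 2 libraries left 2 (0.193 for stromal, 0.115 for erythroid, 0.193 for the imprinted cluster), with fewer members tested. With no filter the imprinted cluster stood at 0.0538, and with entries collapsed the erythroid list at 0.0577. Leaving out 1 infected library left 2 to 4 lists. The camera adjusted p then ran from 0.0987 to 0.148 for erythroid, from 0.0260 to 0.543 for stromal and from 5.1e-04 to 0.935 for the imprinted cluster, whose direction reversed without infected 2. Beyond fewer members or libraries, the cause was not tested.

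List medians kept within the spread between infected libraries in 126 combinations of list and alternative and moved further in 28. Library totals alone gave -0.49 for leukocyte, -0.12 for lactating gland, 0.50 for stromal, -0.44 for endothelial and 0.80 for ruminant miRNAs, and upper quartile factors 0.33 for lactating gland. The minimum of 10 CPM gave -0.075 for lactating gland, 0.42 for stromal and 0.47 for ruminant miRNAs. limma-voom gave 0.75 and collapsed entries 0.75 for the ruminant list. On log2(TPM + 1) the medians were -0.59 for leukocyte, -0.17 for lactating gland, 0.29 for stromal, -0.49 for endothelial, 0.32 for erythroid and 0.38 for ruminant miRNAs. On log2(TPM + 0.1) they were -0.59 for leukocyte, -0.47 for epithelial, -0.17 for lactating gland, 0.42 for stromal, -0.50 for endothelial, -0.30 for miR-17-92 and 0.51 for ruminant miRNAs. The TPM carry no composition factor, and on them the median of all miRNAs moved by -0.36 and -0.42. Leaving out 1 infected library gave 0.74 to 0.88 for ruminant, -0.54 to -0.14 for leukocyte and 0.022 to 0.19 for lactating gland miRNAs. Medians of lists not called changed sign to 0.08 for endothelial and -0.15 for let-7 without infected 2, to -0.07 for miR-17-92 without infected 1 and to 0.13 for epithelial without infected 3. Of 55 named miRNAs, the fitted direction turned in 8 without infected 2, in 7 on the TPM scales and in 6 with library totals alone, and none of these passed a test in the main comparison.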

Other observations

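Chosen only after the results were seen were the tests of a mislabelled library, of near-identical entries and the detection floor for the ruminant list, of normalization and leukocytes for the inflammation list, and of other splits for the number of miRNAs. Some groups of neighbouring miRNA genes, chosen after their values were seen, had fitted values on 1 side of 0. The 4 members of the miR-363, miR-20b, miR-18b and miR-106a cluster had fitted values above 0, with a median log2 fold change of 0.88, and medians of 1.39, -0.03 and 1.10 in infected 1, 2 and 3. The miR-362-3p, miR-362-5p, miR-500 and miR-660 cluster was alike, with 4 of 4 above 0, a median of 0.93, and 1.40, 0.07 and 1.0 in the 3 libraries. The miR-106b, miR-93 and miR-25 cluster, whose hairpins lie in an intron of MCM7, had 0 of 3 above 0 and a median of -0.39, with -1.03, 0.00 and -0.85; miR-106b turned positive with upper quartile factors, without the 5 most abundant miRNAs and without infected 2. None of these miRNAs passed edgeR's test. The hypothesis that neighbouring hairpins change together was tested over 310 miRNAs with a single locus. The mean product of their centred fold changes stood at the 97.28 percentile of 10000 random reassignments for 69 neighbouring pairs outside the imprinted cluster, and at 97.88 with it. Both arms of a hairpin entered as separate members and were reassigned singly, so these percentiles may be too high. Shared transcription of neighbours could give such values but was not tested, and reads shared in part between names were not examined here. The percentiles do not separate infection from the deviations of single libraries.

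Other families separated infected 2 from the other 3 libraries. Set against those, camera with its preset correlation found the imprinted cluster lower in infected 2 (adjusted p 2.47e-08) and the let-7 family higher (adjusted p 0.00292); with an estimated correlation it called 0 lists there. Over 33 hairpins with both arms tested, the log2 ratio of the 5p to the 3p arm in the control lay outside the infected range for 17, where chance gives 50%. For miR-199a that ratio was -1.85 in the control and higher by 1.11 ± 0.13 (SD, n = 3) in the infected libraries. For miR-27a it was higher by 1.67 ± 0.54. Both were chosen after their values were seen. The counts of miR-199a-3p nearly equal those of miR-3604, so the hairpin behind its reads is uncertain.

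The 4 libraries give 4 splits of 1 against 3, the real one included, too few for a share under 0.05. The real count of called miRNAs was 0 and the highest other 0, so 4 of 4 splits match it by construction. At an unadjusted p under 0.05 the control set apart gave 8 miRNAs, infected 1 gave 16, infected 2 gave 39 and infected 3 gave 3. The real split called 5 lists by camera and was the only 1 of the 4 to call as many, the highest other calling 2; with an estimated correlation 0 lists were called in each of the 4 splits. The 63 calls without infected 2 were tested against the hypothesis that a pair of alike libraries sets the spread: infected 2 against infected 1 and 3 called 109 miRNAs, so such calls do not need a control library. Of the 63 and 109, 45 were called in both, all in the same direction, against 8.86 expected for independent lists and at most 1 in 20 simulations of unchanged libraries that share the pair. The simulations used the spread fitted over all 4 libraries, infected 2 included, and not that of the more alike pair infected 1 and 3. They therefore do not show how many shared calls so alike a pair gives by itself, and no conclusion is drawn from them. The covariance of the fold changes was 1.22, against 0.410 in the same simulations, a difference of 0.81. The shared pair cannot be divided so that each part keeps 2 libraries. Part or all of the excess in calls may therefore come from it.

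Infected 2 lay nearer to the control (SD of log2 differences 0.69) than to infected 1 (1.26) or infected 3 (1.07). Unequal depth is argued against, since after thinning to the smallest total the ratio of the smaller infected distance to the control distance was at least 1.503 in 20 draws (1.55 unthinned). Without the 5 most abundant miRNAs the ratio was 1.53 (lower bootstrap bound 1.38). Each miRNA weighs alike in this distance, so leaving out 5 could hardly change it, and that test decides nothing. The pattern was not confined to a few miRNAs. Of 254, infected 2 differed by more than 2-fold from infected 3 in 100 but from the control in 39. A mislabelled library cannot be told apart from an infected one that resembles the control, because the table holds no sign of infection that is independent of the labels. Stage of infection and animal are not in the labels, and no biological explanation was tested.

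The ruminant miR-2284 and miR-2285 list was higher in infected tissue by camera with its preset correlation, which the other p-values here also use, but its adjusted p was 0.639 with an estimated correlation. Entries with near-identical counts are argued against as the whole cause, since with 1 entry per set the median was 0.75 (camera adjusted p 2.71e-04). Members that share only part of their reads have unequal counts, which this test could not detect, so reads shared in part stay open. Members near the detection floor stay open. Over the 15 members with a mean of at least 10 CPM the list's median was 0.37 (camera adjusted p 0.00565, and 0.619 with an estimated correlation). That mean covers 3 infected libraries and 1 control, so it can keep members that are scarce in the control alone. The smaller median shows that scarce members add to the list's size of change. Members that deviate together in single libraries stay open: 0 of 3 infected libraries set against the rest gave a call, but the smallest adjusted p was 0.0655, too near the threshold to exclude it. Infection and a peculiarity of the 1 control library also stay open, since the design confounds them.

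The inflammation-responsive list was lower in infected tissue by camera with its preset correlation, but its adjusted p was 0.639 with an estimated correlation. A scaling factor shifts all miRNAs of a library alike, and camera compares the members with all others, so such a shift alone is argued against. The list's median stood at the 0.12 percentile of random lists matched on mean expression. That percentile repeats camera's comparison and adds no separate support. Random lists also lack the correlation between members, estimated at 0.44 for this list. A smaller share of leukocytes stays open: 6 leukocyte miRNAs outside the list had medians on average 0.67 above it (SD 0.38, n = 3), but only 0.23 above it in infected 2, and the shared members, among them the myeloid miR-223 at -1.86, had fitted values below 0. Members that deviate together in single libraries may account for it, since 2 of 3 infected libraries set against the rest also gave a call (adjusted p 0.0225 for infected 1 and 0.0349 for infected 3), in the direction of lower values in that library, although with an estimated correlation neither library gave a call. An effect of infection stays open, as does the 1 control library.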
